A study of Homo sapiens with 2 samples.

How the data were processed

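RNA of MCF-7 cells, a human breast cancer line, was sequenced in 2 replicate libraries, and 2 result tables per library were used, for genes and for isoforms. Per the labels' protocols, cells were grown in DMEM with fetal bovine serum, total RNA was taken up in TRI reagent, ribosomal RNA was removed with a RiboMinus kit, and the remaining RNA was broken up with RNase III, with no selection for poly(A) tails. Per the submitters' processing notes, STAR and RSEM were used with the human genome build GRCh38. Their versions, their settings, the annotation release and the use of strand are not given in the sources used here.

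The deposited gene and isoform tables hold RSEM's expected counts, estimated read counts that need not be whole because a read that fits several transcripts is divided among them. The deposited TPM values are those counts divided by each transcript's effective length and scaled to the same total in each library. The deposited FPKM values are counts over effective length and library total, and were used in 1 alternative. The deposited isoform tables also give each isoform's percent of its gene's TPM. Effective length is the annotated length less what the fragment length takes away. The difference was 317 nt in replicate 1 and 178 nt in replicate 2 for long transcripts. It shrinks toward 0 as a transcript nears the length of the fragments, which can give a very high TPM from few counts, and where it is 0 the transcript is listed at 0 TPM. A length of 0 held for 9110 of 61860 genes in replicate 1 and 4789 in replicate 2. Genes with an effective length below 50 nt held 79.7% of TPM in replicate 1 from 6.14% of its counts, and 15.5% of TPM in replicate 2 from 0.470% of its counts.

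The libraries had 12623638 and 45659507 estimated counts, with 22499 and 30753 genes above 0. Nuclear protein-coding genes held 91.4% of counts in replicate 1 and 65.9% in replicate 2. A level in replicate 1 rests on fewer reads, so low genes are less precise there: the 3 counts that a count of 0 allows are 0.238 CPM (counts scaled to the library total) in replicate 1 and 0.0657 CPM in replicate 2, by counting error only. Gene identifiers were matched to symbols for 61757 of 61860 genes, and to gene types and GRCh38 positions of GENCODE 29 for 58308. The 103 genes without a symbol held 0.0340% and 0.192% of counts and stayed in all totals. Of 251121 isoforms, 202907 are in that release, and those outside it held 6.67% and 4.97% of counts. Some identifiers are newer than that release, so it is not the annotation the authors used. Positions are given only for genes found in it.

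Both libraries form 1 group. With no second group no differential test was possible, and edgeR 4.0.16 and DESeq2 1.42.0 in R 4.3.3 were used only for scaling factors, from expected counts rounded to whole numbers. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Levels were compared as log2(TPM + 1), that is with a pseudocount of 1, which understates differences of low genes. A gene was called expressed at 1 TPM in both libraries. Genes over 2-fold apart on that scale were counted among those with a mean of at least 100 estimated counts, beside 20 Poisson draws from a shared profile at the depth and effective lengths of each library, with genes at an effective length of 0 in a library counted apart.

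There were 21 gene lists fixed before the data were examined: luminal and estrogen receptor genes, basal and mesenchymal genes, immune, stromal and endothelial markers, proliferation genes, both histone classes, small structured RNAs, long noncoding RNAs, mitochondrial protein-coding and rRNA genes, nuclear rRNA genes, ribosomal protein genes, stress response genes, MCF-7 fusion partners, genes of amplified segments, lost genes, genes known to give circular RNAs, splicing factors, ARFGEF1 and its relatives, and housekeeping genes. A list's level, the mean over libraries of its median log2(TPM + 1), was placed among 10000 random lists of the same size drawn from genes above 0. Since most such genes are near 0, most of the lists stood at the 100 percentile, and the others were the ARF list (99.1), lost genes (51.3), basal genes (8.54), and immune, stromal and nuclear rRNA lists (0). Levels among genes at 1 TPM or more are given where they change a call. The median log2 ratio of a list was placed among 10000 random lists matched on expression in 20 bins. Percentiles below 2.5 or above 97.5 were counted as standing apart. Luminal against basal and replication-dependent against replication-independent histone lists were compared by 100000 permutations of list membership, 2-sided. Windows of 5 Mb with at least 10 protein-coding genes were ranked by median level. GC content was taken from the most abundant isoform, and its trend was removed as running medians over 50 bins of genes.

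The genes named are, by a rule fixed before the data were examined, the 4 highest of each list and members below 1 TPM where there were at most 4, the 10 highest genes and protein-coding genes, the 5 largest differences each way, the main isoforms of 10 genes, and a fixed set around ARFGEF1, the estrogen receptor, the stress response and MCF-7 fusions. TALAM1, MT-ATP8 and the VMP1 isoforms were named after their values were seen, as were the genes of the closing observations that belong to no fixed list.

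The steps were tested on simulated data. Of 10675 genes, 200 were changed in groups of 50 by folds of 1.5, 3, 4 and 8 at the real depths. Over 2-fold apart were 0, 34, 42 and 48 of the 50, all in the right direction, and none of the 10475 unchanged genes. The shortfall at 3-fold and 4-fold comes with the pseudocount, which shrinks low genes. Random lists of 20 genes shifted by 0.5 log2 were found in 100 of 100 trials, and unshifted ones in 3. For list levels, 100 of 100 raised lists and 6 unshifted lists were found. In both trials the lists and their random lists came from nuclear protein-coding genes with a mean of at least 100 counts. The rates therefore do not carry over to the level percentiles given here, which are among all genes above 0. Nor do they carry over to the ratio percentiles of the fixed lists, which are among all genes with counts in either library. A trend over GC content with a Spearman rho of -0.980 fell to -0.0225 after removal, and 3 of 40 contrasts of random lists passed p = 0.05.

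Alternatives covered other pseudocounts, thresholds and scalings, CPM, leaving out each library, and, added after the data were seen, annotated length in place of effective length, nuclear protein-coding genes alone and matching on or removal of GC content. Trans-spliced, fused and circular RNAs were not analysed here, since the tables hold annotated genes and isoforms.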

Results

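MCF-7 is an established human breast cancer cell line of the luminal, estrogen receptor-positive type. The study behind these libraries searched cancer cells for intragenic trans-splicing, the joining of exons from separate transcripts of one gene, and general knowledge of it, not its labels, names ARFGEF1 as the host gene of such an RNA. Short-read RNA-seq of rRNA-depleted RNA that had not been selected for poly(A) tails was collected from MCF-7 cells to help set aside false candidates, gene fusions and circular RNAs. There was 1 group with 2 libraries, replicates 1 and 2, and no second condition, so each question below concerns what RNA these cells held and how far the replicates differed. The estimated counts summed to 12623638 in replicate 1 and 45659507 in replicate 2. The labels do not say whether the replicates were separate cultures, so the spread between them may be technical. Values with ± are means and SD over both libraries (n = 2).

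The first comparison asked whether the libraries carried the expression profile of luminal breast epithelium. Genes of luminal identity and estrogen response were expressed and markers of basal, immune and stromal cells were mostly near 0. Of 30 luminal and estrogen receptor genes, 29 reached 1 TPM in both libraries, with a median of 20.5 TPM in replicate 1 and 28.1 TPM in replicate 2. The exception was BCL2, an inhibitor of apoptosis, at 0.640 ± 0.156 TPM. The epithelial keratin genes KRT8 (1356 ± 263 TPM), KRT18 (1227 ± 8.09 TPM) and KRT19 (564 ± 94.1 TPM) and TFF1, a classical estrogen-induced gene (796 ± 56.7 TPM), led the list. The estrogen receptor gene ESR1 (chromosome 6, 151656691 to 152129619, GRCh38) stood at 27.3 ± 7.69 TPM, the luminal transcription factor gene GATA3 at 41.7 ± 26.4 TPM and the progesterone receptor gene PGR at 2.22 ± 1.07 TPM.

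Of 24 basal and mesenchymal genes, 18 lay below 1 TPM in both libraries and 4 reached it in both. Those 4 were CD44, a cell-surface hyaluronan receptor (10.6 ± 3.77 TPM), the caveolin genes CAV1 (7.60 ± 7.06 TPM) and CAV2 (6.22 ± 4.33 TPM), and the fibronectin gene FN1 (1.56 ± 0.382 TPM). The median log2(TPM + 1) of the luminal list exceeded that of the basal list by 4.53 ± 0.29, and 2-sided permutation of list membership gave p = 1e-05, the smallest value that 100000 resamples can give. Genes are not independent replicates, so this p describes the lists and not the variation among cultures. All 16 immune cell markers lay below 1 TPM in both libraries, the highest being HLA-DRA at 0.710 ± 0.269 TPM, followed by CD14 (0.0750 ± 0.0354 TPM), CD79A (0.0650 ± 0.00707 TPM) and CD68 (0.0350 ± 0.0495 TPM). Among 15 stromal and endothelial markers, 14 were below 1 TPM in both, including COL1A1 (0.610 ± 0.297 TPM), RGS5 (0.0900 ± 0.0849 TPM) and KDR (0.0200 ± 0.0141 TPM). The exception was the fibrillar collagen gene COL3A1, at 12.6 TPM in replicate 1 and 17.6 TPM in replicate 2.

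**Figure D1:**
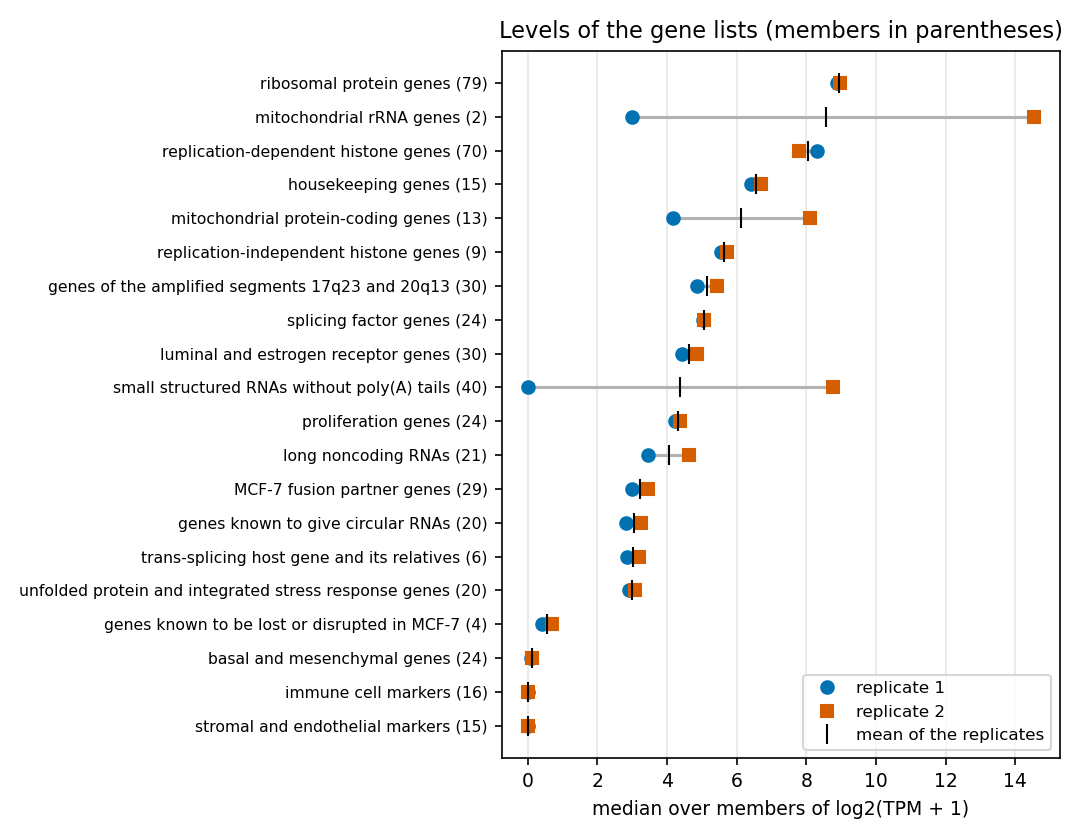
Median log2(TPM + 1) over the members of each gene list in replicate 1 (circles) and replicate 2 (squares), with the mean of both as a vertical tick and the number of members in parentheses. The luminal list lies at 4.64 and the basal list at 0.11 on average, while the mitochondrial lists and the small structured RNAs sit far apart in the replicates.

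MCF-7 cells are known to have lost or disrupted a few genes and to have amplified others, and the next comparison asked how these read in RNA. The cell cycle inhibitor gene CDKN2A (chromosome 9, 21967753 to 21995301) was at 0.130 ± 0.141 TPM, its neighbours MTAP, an enzyme gene of methionine salvage, at 0.310 ± 0.297 TPM and CDKN2B at 0.665 ± 0.120 TPM. CASP3, which encodes an executioner caspase, reached 1.04 TPM and 1.71 TPM. CDKN2A rested on 1 count in replicate 1 and 16.1 in replicate 2, so its level is imprecise.

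Genes of the amplified segments 17q23 and 20q13 were high: 27 of 30 reached 1 TPM in both libraries, and the list had a median of 28.1 TPM in replicate 1 and 42.7 TPM in replicate 2. The highest were PFDN4, a prefoldin subunit gene (159 ± 51.7 TPM), CLTC, which encodes clathrin heavy chain (155 ± 11.9 TPM), VMP1, an autophagy gene (152 ± 114 TPM), and TRIM37, a ubiquitin ligase gene (140 ± 35.6 TPM). Much of the VMP1 value was assigned to retained-intron transcripts. Its leading protein-coding isoform, ENST00000262291, stood at 18.65 TPM in replicate 1 and 37.5 TPM in replicate 2. CYP24A1 (0.190 ± 0.156 TPM) and DOK5 (0.0250 ± 0.0354 TPM) were the members below 1 TPM in both. Known MCF-7 fusion partner genes overlap this list. Of 29 found, 26 reached 1 TPM in both libraries, led by VMP1, SULF2, an extracellular sulfatase gene (137 ± 34.2 TPM), BCAS3 (104 ± 26.9 TPM) and RPS6KB1, the S6 kinase gene (101 ± 19.2 TPM), while MSI1 (0.685 ± 0.163 TPM) and RGS17 (0.620 ± 0.481 TPM) stayed below it. BCAS4, the partner of BCAS3 in the best known MCF-7 fusion, was at 10.5 ± 0.658 TPM, and ARFGEF2, the partner of SULF2, at 8.05 ± 1.05 TPM. Fused transcripts were not separated from normal ones in these estimates.

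By position, protein-coding genes between 60 and 65 Mb of chromosome 17 had a median log2(TPM + 1) of 2.68 ± 0.50, which ranked 8 among 521 windows of 5 Mb, against 0.99 for all protein-coding genes. The window from 50 to 55 Mb of chromosome 20 reached 2.55 ± 0.30 and ranked 14. From 55 to 60 Mb the median was 2.10 ± 0.28 on chromosome 17, rank 47, and 1.79 ± 0.35 on chromosome 20, rank 103. The window from 45 to 50 Mb of chromosome 20, which holds SULF2, was at 0.30 ± 0.16 and ranked 404. High windows were not limited to the amplified segments. The window from 50 to 55 Mb of chromosome 17 was at 2.58 ± 0.26 and ranked 11. The highest of all, from 105 to 110 Mb of chromosome 14, was at 3.14 ± 0.03. When genes below 1 TPM were left out, the windows from 55 to 60 Mb moved to the 99.1 percentile on chromosome 17 and the 98.5 percentile on chromosome 20.

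**Figure D2:**
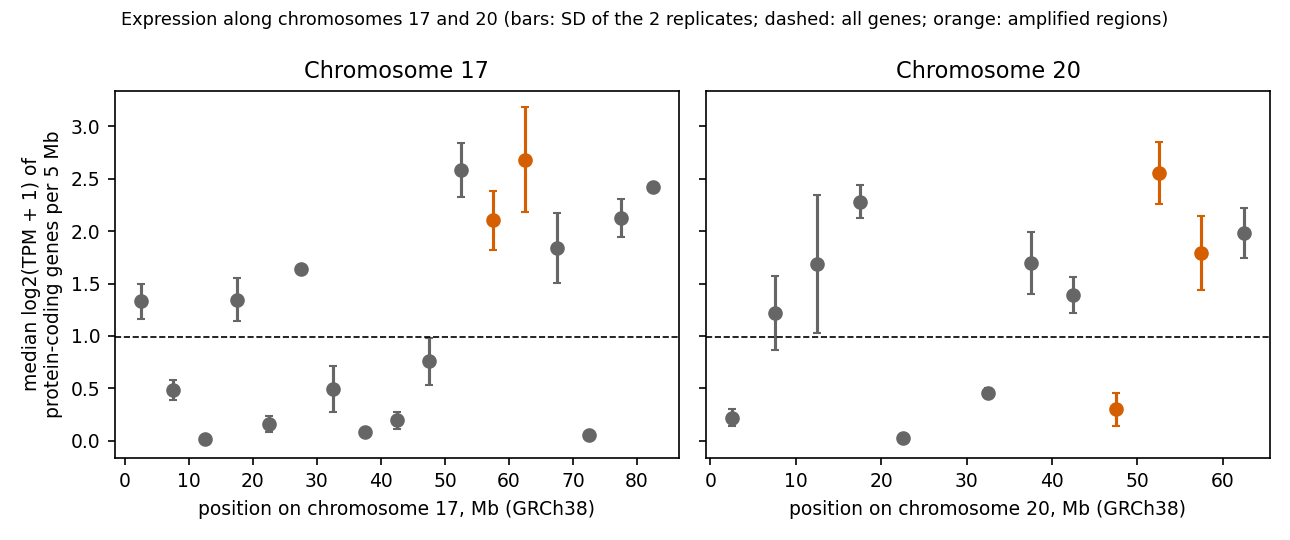
Median log2(TPM + 1) of protein-coding genes in 5 Mb windows along chromosomes 17 and 20 (GRCh38), as mean and SD of the 2 replicates, with the windows of the amplified regions in orange and the median of all genes dashed at 0.99. The windows from 60 Mb on chromosome 17 (2.68) and from 50 Mb on chromosome 20 (2.55) lie above that line and the window from 45 Mb on chromosome 20 (0.30) lies below it. The unmarked window from 50 Mb on chromosome 17 (2.58) is as high.

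ARFGEF1, the gene so named, was expressed at a low to moderate level in both libraries. The gene (ENSG00000066777, chromosome 8, 67173511 to 67343677, minus strand) encodes a guanine nucleotide exchange factor for ARF proteins at the Golgi. It had 4.12 TPM from 1343 estimated counts in replicate 1 and 7.13 TPM from 4704 counts in replicate 2, or 106 and 103 counts scaled to the library total (CPM). The protein-coding isoform ENST00000262215 (7320 nt) made up 82.7% of the gene's TPM in replicate 1 and 87.3% in replicate 2, and the short isoform ENST00000519436 (571 nt) 9.45 ± 3.95%, which rested on 7.02 counts in replicate 1. A trans-spliced isoform is not among the 8 isoforms listed for the gene and was not analysed here. All 6 genes of the ARF and ARF-exchange-factor list reached 1 TPM in both libraries, with ARF1 at 54.3 ± 5.98 TPM, ARF3 at 26.1 ± 1.80 TPM, ARFGEF2 at 8.05 ± 1.05 TPM and GBF1 at 6.42 ± 1.65 TPM.

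The next comparison concerned the unfolded protein response, to which general knowledge of the study, and not its labels, links the trans-spliced ARFGEF1 RNA. Genes of this response were expressed at moderate levels. Of 20 genes of the unfolded protein and integrated stress response, 18 reached 1 TPM in both libraries, with list medians of 6.45 and 7.55 TPM. The highest were XBP1 (316 ± 42.9 TPM), the chaperone genes CALR (85.7 and 142 TPM) and HSP90B1 (61.1 ± 14.5 TPM), and EIF2S1, which encodes the translation factor that the stress kinases phosphorylate (58.5 ± 0.566 TPM). The kinase gene EIF2AK3 (PERK) stood at 5.70 ± 1.80 TPM, the transcription factor gene ATF4 at 38.8 ± 0.863 TPM, its target DDIT3 (CHOP) at 3.19 ± 0.849 TPM and the chaperone gene HSPA5 (BiP) at 25.1 ± 7.49 TPM. The stress-induced genes CHAC1 (0.685 ± 0.389 TPM) and ATF3 (0.235 ± 0.0919 TPM) were below 1 TPM in both. Among genes at 1 TPM or more the list's level was at the 85.4 percentile of random lists, and that of the ARF list at the 68.9 percentile.

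Because poly(A) selection was left out, the next comparison looked at RNAs without poly(A) tails. Small structured RNAs held 77.1% of all TPM in replicate 1 and 61.7% in replicate 2, but 6.04% (95% Wilson interval 6.03 to 6.06) and 17.1% (17.09 to 17.11) of the estimated counts. These intervals cover counting error only. The highest genes were the signal recognition particle RNA genes RN7SL2 (330249 ± 125409 TPM) and RN7SL1 (152111 ± 72159 TPM), RN7SK, a regulator of transcription elongation (112549 ± 66313 TPM), RMRP (36345 ± 31182 TPM) and RPPH1, the RNase P RNA gene (28325 ± 641 TPM). These TPM values depended on the short length left for counting, most of all in replicate 1. RN7SL2 (chromosome 14, 49862550 to 49862849) is 300 nt long and its effective length, the number of positions where a fragment can start, was 14.9 nt in replicate 1 and 126 nt in replicate 2. When counts were divided by annotated length instead, a scale chosen after the data were seen, the class held 26.1% and 51.6%, so replicate 2 had the larger share on that scale, as by counts, and the smaller share of TPM.

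Of the 40 small structured RNA genes, 26 had an effective length of 0 in replicate 1 and were listed at 0 there whatever their abundance. The spliceosomal RNA genes RNU4-2 and RNU2-2P were among them, and stood at 10326 TPM and 7098 TPM in replicate 2. The 10 highest genes also included MT-RNR2, MT-RNR1, the RN7SL3 gene (10717 ± 3163 TPM), RNU4-2 and the lincRNA gene ENSG00000269900 (8759 ± 2718 TPM), which has no symbol. The 10 highest genes of each library by TPM took 79.7% of TPM in replicate 1 and 62.7% in replicate 2. The 10 highest of each library by estimated counts, which need not be the same genes, took 10.1% and 31.1% of counts. RN7SL1, RN7SL2 and RN7SL3 are near-identical copies, so the division of reads among them is uncertain. The same holds for RMRP (chromosome 9, 35657754 to 35658017) and ENSG00000269900 (35657751 to 35658018), which lie on the same strand and cover the same bases.

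**Figure D3:**
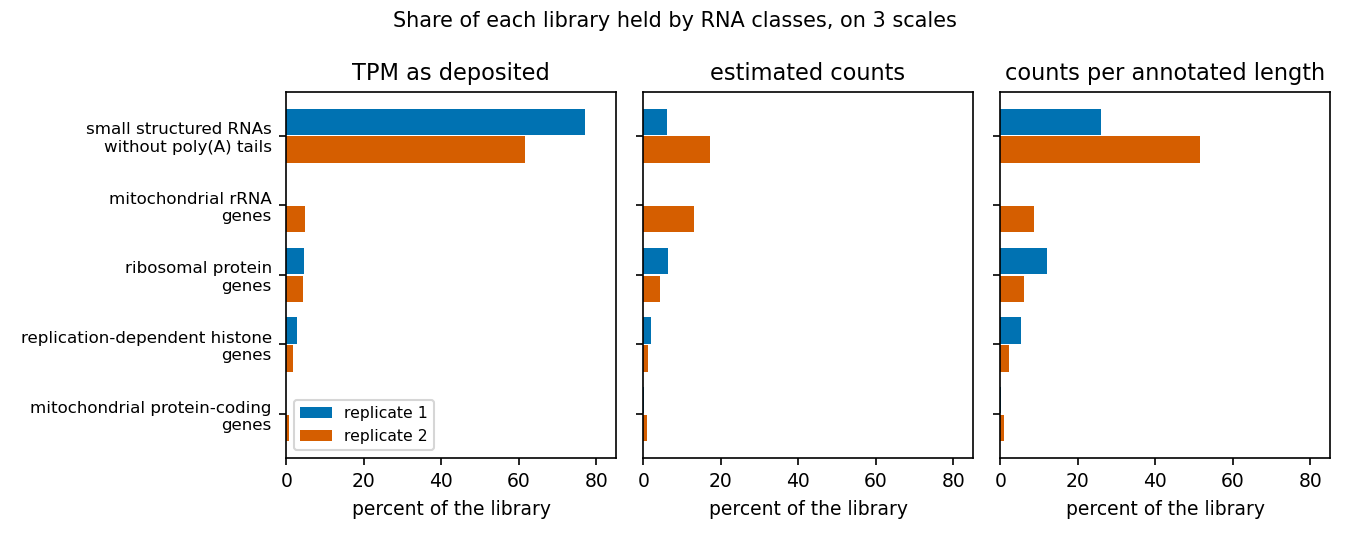
Percent of each library held by 5 RNA classes by deposited TPM, by estimated counts and by counts per annotated length, for replicate 1 (blue) and replicate 2 (orange). Small structured RNAs hold 77.1% of TPM and 6.04% of counts in replicate 1, and mitochondrial rRNA is visible in replicate 2 alone.

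Replication-dependent histone genes, whose mRNAs end in a stem-loop and not in a poly(A) tail, were among the most abundant mRNAs by TPM. Of 70 such genes, 61 reached 1 TPM in both libraries, with medians of 314 TPM in replicate 1 and 220 TPM in replicate 2. H4C14 (1598 ± 923 TPM), H4C15 (1582 ± 906 TPM), H2AC18 (1236 ± 463 TPM) and H3C15 (1121 ± 461 TPM) were highest, and H4C3 stood at 756 ± 505 TPM. H4C14 and H4C15 are near-identical copies, as are other members, so single-gene values are uncertain. Their rank also rested on short effective lengths, 102 nt for H4C14 in replicate 1 and 251 nt in replicate 2. By CPM, H4C14 stood at 998 and 529, and the long mRNA of EEF1A1 at 13736 and 7431. The 9 replication-independent histone genes, led by H3-3B (520 ± 130 TPM), H2AZ1 (329 ± 29.6 TPM), H3-3A (93.2 ± 31.5 TPM) and H2AZ2 (58.9 ± 16.6 TPM), lay lower: the difference of the list medians was 2.41 ± 0.47 log2 (2-sided permutation p = 0.0239 across genes). The call depended on the correction for length: the difference was -0.05 log2 by CPM (permutation p = 0.956) and 1.51 log2 by annotated length (permutation p = 0.0616).

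Of 21 long noncoding RNA genes, 16 reached 1 TPM in both libraries. DSCAM-AS1, an antisense RNA gene of estrogen receptor-positive breast cancer, stood at 265 ± 53.2 TPM, MALAT1 at 201 ± 92.8 TPM, GAS5 at 113 ± 16.6 TPM and NEAT1 at 7.85 ± 8.30 TPM. BCYRN1 was listed at 0 in replicate 1, where its effective length was 0, and at 2099 TPM in replicate 2. MIR17HG (0.620 ± 0.438 TPM), KCNQ1OT1 (0.565 ± 0.191 TPM) and MEG3 (0.0350 ± 0.0495 TPM) lay below 1 TPM in both. TALAM1, annotated antisense to MALAT1 and named after its values were seen, drew more counts than MALAT1, 11627 against 4851 in replicate 1 and 67704 against 32133 in replicate 2. The use of strand in counting is not given in the sources used here, so the 2 genes cannot be separated with certainty.

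Mitochondrial RNA separated the replicates most clearly. The mitochondrial 16S rRNA gene MT-RNR2 (positions 1671 to 3229) stood at 2.94 TPM from 200 counts in replicate 1 and at 35306 TPM in replicate 2, and the 12S rRNA gene MT-RNR1 (positions 648 to 1601) had 383 and 998087 counts. Together they held 0.00462% of the counts in replicate 1 and 13.1% in replicate 2. The 13 mitochondrial protein-coding genes, which encode respiratory chain subunits, were all higher in replicate 2 as well, MT-ATP8 being listed at 0 in replicate 1 at an effective length of 0, with medians of 17.01 and 275 TPM and a median log2 ratio of 3.73. MT-CO3 stood at 78.3 and 1475 TPM, MT-CO1 at 116 and 1107 TPM, MT-CO2 at 71.96 and 1104 TPM and MT-ND3 at 87.6 and 466 TPM. Against 10000 random lists matched on expression, the median ratio of the protein-coding list lay at the 100 percentile. Of 543 nuclear rRNA genes, 534 lay below 1 TPM in both libraries. However, all 543 had an effective length of 0 in replicate 1 and 144 in replicate 2, so their abundance was not measured there. The list therefore held short copies only and says nothing about the longer nuclear rRNAs. The 5.8S genes RNA5-8SN1, RNA5-8SN2, RNA5-8SN3 and the 5.8S copy ENSG00000277739 led that list at 182 TPM each in replicate 2, near-identical copies that share their reads.

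Genes of growth and basic cell function were highly expressed in both libraries. All 24 proliferation genes reached 1 TPM in both, with medians of 17.8 and 19.8 TPM, led by the replication genes PCNA (67.0 ± 5.73 TPM) and MCM7 (59.2 ± 8.14 TPM) and the mitosis genes CCNB1 (56.5 ± 0.495 TPM) and AURKA (45.4 ± 2.47 TPM). All 79 ribosomal protein genes did so too, with medians of 467 and 504 TPM, RPL41 (1567 ± 28.8 TPM), RPL39 (1441 ± 373 TPM), RPS27 (1428 ± 331 TPM) and RPS21 (1371 ± 760 TPM) being highest. All 15 housekeeping genes reached 1 TPM in both, and EEF1A1 (2081 ± 67.1 TPM), GAPDH (992 ± 197 TPM), PPIA (736 ± 205 TPM) and ACTB (489 ± 205 TPM) led. Genes annotated as protein-coding in GENCODE 29 were also ranked by mean TPM, with ribosomal protein and mitochondrial genes left out. The histone gene H2AC18 (1236 ± 463 TPM) is not in that release and was therefore not ranked, although its mean exceeds that of KRT18. The 10 highest were EEF1A1, H4C14, H4C15, KRT8, KRT18, H3C15, GAPDH, TFF1, the myosin light chain gene MYL6 (791 ± 173 TPM) and H4C3. The places of short genes depended on effective length. In replicate 1 it was 82.8 nt for RPL39, 50.3 nt for RPS27, 55.8 nt for RPS21 and 94.3 nt for H4C3.

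All 24 splicing factor genes reached 1 TPM in both libraries, with medians of 31.98 and 32.5 TPM. HNRNPC (295 ± 37.4 TPM), HNRNPA1 (251 ± 73.9 TPM), SRSF3 (101.5 and 118 TPM) and SNRPB (92.7 ± 20.9 TPM) were highest. Of 20 genes known to give circular RNAs, 18 reached 1 TPM in both, with RHOBTB3 (32.9 ± 14.5 TPM), SETD3 (19.9 ± 1.87 TPM), VRK1 (19.3 ± 3.07 TPM) and CDYL (16.1 ± 2.18 TPM) at the top and CDR1 (0.0800 and 0.0200 TPM) below 1 TPM. The estimates are for whole genes and do not separate circular from linear RNA. Beside genes at 1 TPM or more, the level of this list was at the 90.7 percentile of random lists.

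The isoform tables were used to ask how evenly genes spread their RNA over isoforms. Among 9375 genes with at least 2 isoforms and 1 TPM in both libraries, the most abundant isoform held a median of 57.8 ± 1.29% of the gene's TPM, and it was the same isoform in both libraries for 7151 genes (76.3%). XBP1 was concentrated in ENST00000216037 (91.6 ± 2.56%), PKM in ENST00000335181 (82.3 ± 4.04%), ESR1 in ENST00000206249 (75.2 ± 12.3%) and GATA3 in ENST00000379328 (71.4 ± 14.1%). CD44 (ENST00000433892, 25.6 ± 4.55%), BCL2L1 (ENST00000307677, 26.1 ± 18.4%) and QKI (ENST00000361758, 19.3 ± 21.8%) were spread over many, and in replicate 1 other isoforms led BCL2L1 and QKI. BCAS3 was dominated by ENST00000592702, a noncoding processed transcript of 2094 nt (63.8 ± 1.77%). RPS6KB1 changed its leading isoform, from ENST00000443572 (48.8%) in replicate 1 to ENST00000225577 (37.7%) in replicate 2. The retained-intron transcript ENST00000592790 of VMP1, named after its values were seen, held 24.8% in replicate 1 and 58.2% in replicate 2.

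The last comparison asked how far the replicates agreed. Across 31421 genes with counts, log2(TPM + 1) correlated with Pearson r = 0.918 and Spearman rho = 0.860, a statement across genes, which are not independent replicates. Across 10678 nuclear protein-coding genes with a mean of at least 100 counts, r was 0.964 and rho 0.951, and replicate 2 was higher by a median of 0.28 log2. In both libraries, 9999 genes reached 1 TPM, of which 9400 were protein-coding.

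Of 11592 genes with a mean of at least 100 counts, 758 differed by more than 2-fold, 705 higher and 53 lower in replicate 2. Of the tested genes, 58 had an effective length of 0 in a library, which by itself sets them apart. Among the other 11534, 701 differed by more than 2-fold, 648 higher and 53 lower in replicate 2, where 20 Poisson draws at the same depths gave a mean of 0.5 and at most 1. The draws hold counting error alone and no variation among libraries or cultures. With the median shift of nuclear protein-coding genes taken out, 400 differed, 287 higher and 113 lower, and by CPM scaled with the trimmed mean of M values there were 553, 381 higher and 172 lower. DESeq2 size factors gave 568, 349 higher and 219 lower. Among nuclear protein-coding genes alone, centring left 263, and removing the trend over GC content left 173, an alternative chosen after the data were seen.

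The largest values in favour of replicate 2 were MT-RNR2 and the small RNA genes RNU4-2, SNORA63, RNVU1-7 and RNU2-2P, the last 4 listed at 0 in replicate 1 at an effective length of 0. In favour of replicate 1 they were ENSG00000259132 (8.59 and 0.0200 TPM), ENSG00000270066 (86.9 and 9.63 TPM), SCARNA13 (2577 and 398 TPM), a copy of MATR3 listed under its own identifier (11.3 and 0.920 TPM) and the pseudogene HMGN2P5 (170 and 34.8 TPM). SCARNA13 and HMGN2P5 had effective lengths of 4.16 and 3.56 nt in replicate 1, and the MATR3 copy shares sequence with the main MATR3 gene, so these values are uncertain. The value of ENSG00000259132, from 243 and 1.27 counts, is uncertain too, since the gene overlaps another gene on the same strand.

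**Figure D4:**
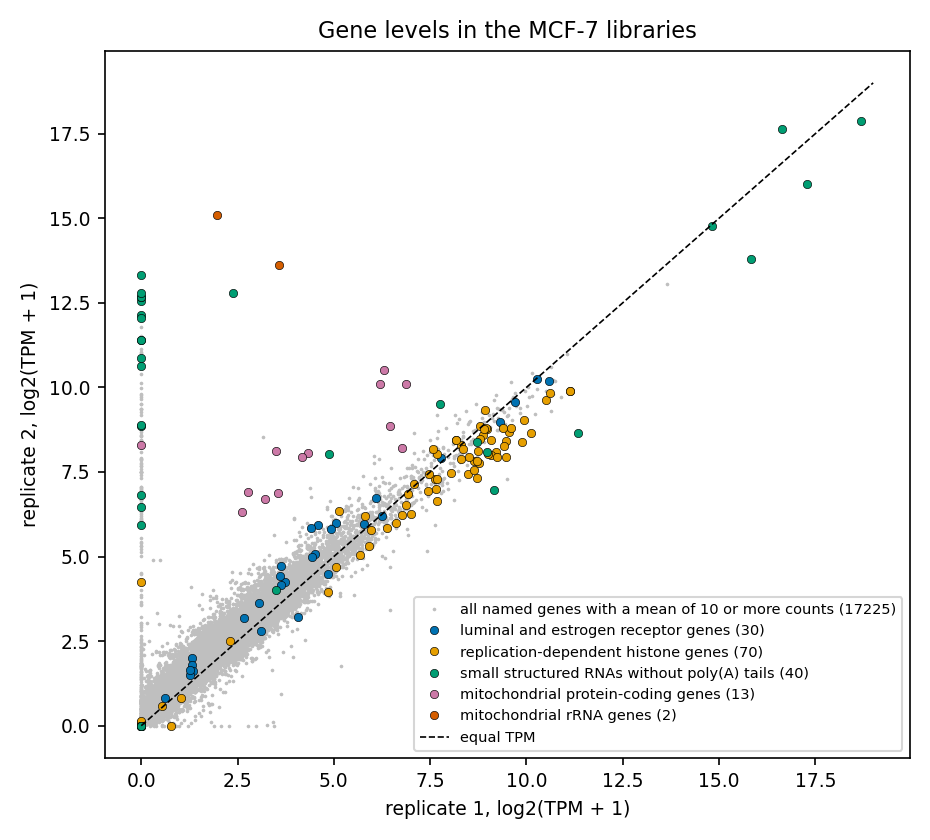
Level of each gene in replicate 1 (x axis) and replicate 2 (y axis) as log2(TPM + 1), with 5 gene lists in colour and a dashed line at equal TPM. Mitochondrial genes and many small structured RNAs lie above the line, the latter at 0 in replicate 1, while replication-dependent histone genes lie mostly below it.

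Among the fixed lists, the median log2 ratio of replicate 2 over replicate 1 lay beyond 97.5% of expression-matched random lists for mitochondrial protein-coding genes, mitochondrial rRNA genes (11.58), long noncoding RNAs (0.65) and genes of the amplified segments (0.51). For nuclear rRNA genes and small structured RNAs the ratio was not read as a difference, because all 543 and 26 of 40 members had an effective length of 0 in replicate 1, which sets them to 0 TPM there. It lay below the lowest 2.5% for replication-dependent histone genes (-0.59, with 54 of 67 lower in replicate 2), ribosomal protein genes (-0.04, with 43 of 79 lower but 6 over 2-fold higher and 2 over 2-fold lower) and basal genes (0.00, with 11 higher and 8 lower). The calls for ribosomal protein, basal and amplified-segment genes ended when CPM scaled by the trimmed mean of M values was used, where the percentiles were 30.1, 30.7 and 96.1. The other lists lay in between: luminal genes at the 96.9 percentile, fusion partner genes at 95.5, replication-independent histone genes at 88.4, splicing factor genes at 85.3, lost genes at 84.7, genes giving circular RNAs at 73.6, housekeeping genes at 52.4, ARF genes at 51.4, proliferation genes at 39.8, immune markers at 27.5, stromal markers at 18.04 and stress response genes at 14.5.

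Across 10675 nuclear protein-coding genes the ratio followed GC content, with a Spearman rho of -0.521 across genes. The median log2 ratio was 0.67 among genes with GC content of at most 39.2% and 0.06 among those of at least 61.8%.

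**Figure D5:**
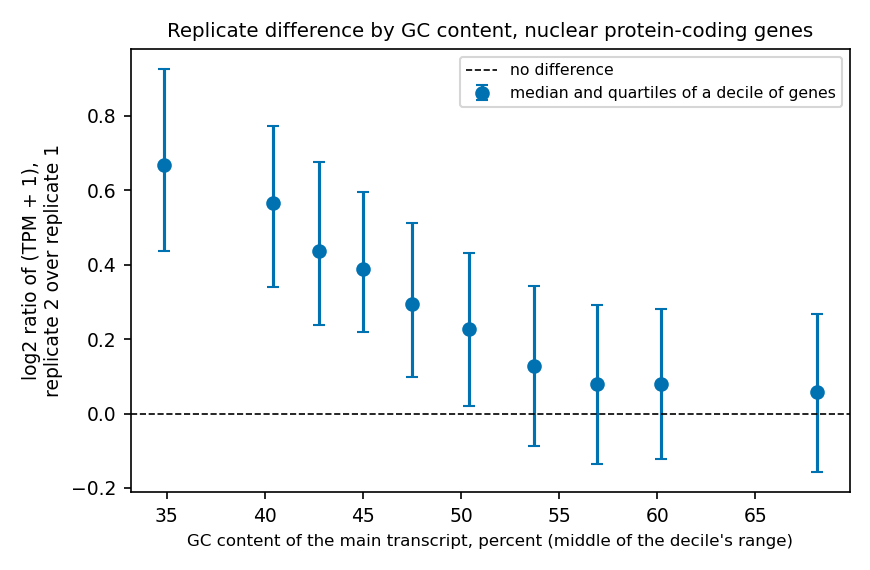
Median log2 ratio of replicate 2 over replicate 1 in 10 groups of nuclear protein-coding genes ordered by GC content of the main transcript (x axis, percent), with bars from the lower to the upper quartile and a dashed line at no difference. The median is 0.67 in the group with the lowest GC content and 0.06 in the group with the highest.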

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

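In all, 253 values were recomputed under alternatives that used both libraries. Of these, 174 kept their call or stayed within a limit, 62 moved past the limit, 11 lost their call, 5 gained one and 1 reversed. The limit was the spread between replicates for shares, isoform shares and single genes. For the correlation it was a fixed difference, and for counts of genes a fixed fold, which is a wide margin. Another 96 values leave out a library. A mean of both libraries always moves by less than their SD then, so those values say nothing about the stability of shares and single genes. Alternatives on annotated length, GC content, nuclear protein-coding genes alone and rescaling within them were chosen after seeing the data, and the others before. The difference of luminal from basal genes kept its call throughout, at 3.88 to 7.04 log2, with p from 1e-05, the smallest the permutations can give, to 0.00012. Unless a cause is given, the cause was not tested.

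The correlation of the replicates was 0.784 among genes at a mean of 1 TPM, 0.981 by CPM and 0.964 among nuclear protein-coding genes with 100 counts. At 0.1 TPM, 15907 genes were detected, a looser threshold by construction. Over 2-fold apart were 421 genes at a mean of 1000 counts, where fewer genes were tested, and 173 nuclear protein-coding genes with the GC trend removed. The count was higher at a mean of 10 counts (956) and with TPM rescaled within nuclear protein-coding genes (1092, 1031 of them higher in replicate 2).

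The level of small structured RNAs fell to the 95.75 percentile by CPM. Leaving out a replicate put it between 0.015, without replicate 2, and 100, because 26 of 40 members have an effective length of 0 in replicate 1. Mitochondrial rRNA ranged from 92.22, without replicate 2, to 100. Among genes at 1 TPM or more, levels of the stress response list (85.37), genes giving circular RNAs (90.69) and the ARF list (68.87) were no longer at the top, because the comparison lists were then expressed, and the 4 basal genes left moved from 8.54 to 51.02. The histone difference was -0.0522 log2 by CPM and 1.51 by annotated length.

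Shares of TPM depended on the scale in most lists. By counts, annotated length and TPM without mitochondrial, rRNA and small structured RNAs, luminal genes held 2.13, 1.54 and 1.89%, and ribosomal protein genes 5.33, 9.12 and 16.7%. Replication-dependent histones held 3.81% by annotated length and 8.78% of that reduced total. By counts and annotated length, small structured RNAs held 11.6 and 38.8%, and the 10 genes highest on each scale 20.6 and 44.8%. Mitochondrial rRNA held 6.54% of counts, and its share of TPM was 0.00139% without replicate 2 and 4.79% without replicate 1.

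For ratios between replicates, the luminal list passed the highest 2.5% with a pseudocount of 0.1 (98.93), at a mean of 10 counts (97.52) and with lists matched on GC content (99.62). The basal list lost its call with scaling by the trimmed mean of M values (30.74) and at 10 counts (15.875), the ribosomal protein list with that scaling (30.125), at 10 counts (10.77) and with GC matching (2.76), and the amplified segments with that scaling (96.12). The main isoform held 65.0% in genes at 10 TPM. ARFGEF1 stood at 104.69 CPM and 16.89 FPKM, other units by construction. Among genes at 1 TPM or more, the windows from 55 Mb reached the percentiles 99.11 on chromosome 17 and 98.52 on chromosome 20.

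Agreement and ratios between replicates need both libraries, so leaving one out was not possible there. The depth of replicate 1, 12623638 counts, limits low genes, and its fragment length limits short ones.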

Other observations

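In this part, the tests of the mitochondrial genes, of GC content, of length and of overlapping genes were chosen only after the result was seen. With 1 group, no biological explanation was tested, and the labels do not say whether the replicates were separate cultures. No paired analysis was possible because each replicate is a single library.

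After the trend over GC content was taken out, FOS (0.460 and 4.13 TPM in replicates 1 and 2), EGR1 (0.120 and 1.31 TPM) and TXNIP (14.7 and 67.4 TPM) were higher in replicate 2, and SLC7A5 (14.2 and 5.98 TPM) and PHGDH (7.40 and 3.97 TPM) were lower. These genes were chosen after their values were seen. They and other genes seen before set the directions tested next on 4 lists that left out the genes seen, ATF3 of the stress response list excepted. The 15 immediate-early genes lay at the 99.55 percentile of lists matched on expression and GC content. Counts of members cover those with a mean of at least 100 counts. Of these, 11 of 11 immediate-early genes were higher in replicate 2, by TPM and also once the GC trend was removed. KLF4 (4.64 and 13.4 TPM) and IER3 (51.8 and 92.6 TPM) were among them. By TPM the list's median log2 ratio was 0.37, against a shift of 0.28 for nuclear protein-coding genes. The 20 amino acid response genes lay at 1.10, with 14 of 17 lower once the GC trend was removed but 10 of 17 by TPM, and SLC38A2 (14.7 and 69.1 TPM) the other way. The 24 ribosome biogenesis genes lay at 0.460, with 20 of 24 lower once the trend was removed but 13 of 24 by TPM.

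Among nuclear protein-coding genes matched on length too, a test added after these results, the percentiles of those lists were 99.74, 0.640 and 0.950, while interferon-stimulated genes, at 19.405 and 43.4, decided nothing. Of lists tested without a prediction, nuclear-encoded respiratory chain genes were as low (0.0900 and 0.975, 26 of 33 lower once the trend was removed and 19 of 33 by TPM), and cholesterol synthesis genes were at 0.590 and 11.8. Of the fixed lists, luminal genes (98.7), replication-independent histone genes (98.5) and amplified-segment genes (98.99) were also high against length-matched lists, replication-dependent histone genes were at 0, proliferation genes at 40.7, ribosomal protein genes at 93.4 and the 8 basal genes with enough counts at 89.06, the other side from their place among all matched lists. Genes of 1 pathway vary together, which random lists do not allow for, and what lies behind these differences was not tested.

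Mitochondrial mRNAs over 500 nt had a median log2 ratio of 3.76 in favour of replicate 2, above the highest 2.5% of nuclear genes of the same length (1.17), so the longer fragments of replicate 1 do not account for it. GC content does not either, with a median of 3.73 for all 13 against 1.13 at the same limit in nuclear genes of like GC content. The smallest ratio of a mitochondrial mRNA, 1.46 for MT-ND4L, lay above the limit of 1.16 for nuclear genes, which argues against a depletion of rRNA alone. Both mitochondrial rRNAs differed more than any mRNA, the smaller by 10.04 log2 against 4.61 for MT-ATP6 and 8.29 for MT-ATP8, which is listed at 0 in replicate 1 at an effective length of 0, but that comparison was chosen from these values and decides nothing. The labels give the same rRNA depletion for both libraries. Why mitochondrial RNA differed between them stays open, as does which of the libraries departs from the usual level.

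Among nuclear protein-coding genes, the log2 ratio followed GC content with a Spearman rho of -0.52, and removing the trend took out 24.9% of the variance, lowered the SD from 0.43 to 0.37 log2 and lowered the number of genes over 2-fold apart from 263, counted around the median, to 173. Across all these genes the ratio hardly followed length, with a partial rho of 0.0406 at fixed GC content. That value cannot exclude an effect confined to short genes. With the GC trend removed, ribosomal protein genes stood at the 42.8 percentile of expression-matched lists, and at 93.4 once length was matched too. Of the 10 genes still over 4-fold apart, 9 (90%) overlapped another gene on the same strand, against 34.2% of all genes and at most 60% in the middle 95% of random sets. Among them were SUMO2 (20.3 and 107 TPM), RPL28 (19.8 and 129 TPM) and the readthrough gene RPL36A-HNRNPH2 (0.40 and 29.1 TPM). Reads divided among overlapping genes may account for values such as that of RPL36A-HNRNPH2, with 5.56 and 1138 counts, which was not tested gene by gene. The counts of SUMO2, 2295 and 9048, rose about as much as the library totals of 12623638 and 45659507. A gain of reads alone therefore does not account for its gap in TPM, most of which comes with effective length and the scaling of TPM. ATP5ME (716 and 156 TPM), with 646 and 2062 counts, was the gene without an overlap. Its counts rose nearly as much as the library totals. Most of its gap in TPM therefore comes with effective length, by which TPM divides counts.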
